A study of Aspergillus flavus with 8 samples.

How the data were processed

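The series holds 8 one-colour microarrays of the filamentous fungus Aspergillus flavus, an aflatoxin producer, grown with or without Bacillus megaterium, a bacterium of marine origin used as an antagonist. There were 4 environments. PDB (potato dextrose broth) and MM (a glucose minimal salts medium) were liquid cultures kept for 48 h at 28 °C and 200 rpm. Jinhua and UF were wounded kernels of peanut lines named by the labels as susceptible and resistant (short names here, in full on the plots), kept for 7 days at 28 °C and 85% humidity with the bacterium applied 2 h before the fungus, with 20 kernels per test and 3 tests per treatment. Each environment gave 1 treated and 1 control array, so each of the 8 groups has 1 array. Sample groups were taken from the labels.

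Per the labels' protocols, RNA was extracted with Trizol, cleaned on a QIAGEN column and labelled with Cy3 by Agilent's one-colour method. Agilent Feature Extraction 10.7.1.1 was used on the scans, per the file headers. The processed intensity of each spot is background-subtracted and spatially detrended but not scaled between arrays, per the file headers, and it was written with few significant digits. The raw mean intensity and the local background intensity were also deposited. The flags for spots well above background, saturated or non-uniform are values of 0 or 1, per the file headers. The authors also deposited a table of log2 values per probe, whose normalization software is not given in the sources used here. Set against the scanner values, these log2 values ran in the same direction on every array (Pearson r 0.997 to 0.999 over 13487 probes). Their medians were 6.75, 6.75, 6.75 and 6.76 for PDB treated, PDB control, MM treated and MM control, and 6.61, 6.61, 6.60 and 6.61 for Jinhua treated, Jinhua control, UF treated and UF control. Medians were nearly equal within each of these sets of 4 columns and differed between them, so this table was not used to set kernels against broths. The genome build behind the probes is not given in the sources used here, and no coordinates are given. None of the gene tags matched the reference gene table (0 genes), so gene names are those of the array's own annotation plus cluster symbols fixed by tag. AFLA_081490, fixed as velB, carries the product name nucleoside diphosphatase Gda1 and is not called velB.

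The array holds 1 probe for each of 13487 genes, of which 5612 are hypothetical proteins, in 15197 spots (190 probes were spotted 10 times). No spot was saturated (0 spots). Values were log2 of the processed signal minus the 75th percentile of the same array. Spots marked as outliers were left out, spots of one probe were averaged, and 11 genes were left out for such a spot. Genes well above background on at least 2 of the 8 arrays were tested (12351 genes). Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. The response across environments was the treatment coefficient of a fit with environment as a block (3 residual degrees of freedom). The broth response, the kernel response and their difference came from 1 fit of the 4 treated-to-control log2 ratios (2 residual degrees of freedom), and kernels against broths from a fit of the 4 environment means. MM against PDB and UF against Jinhua were contrasts of the blocked fit, whose spread is that of the treatment effect between environments. No label says that arrays of different environments came from separate repeats of an experiment, so p-values measure only the spread between these environments. The number of arrays limits the precision.

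Within an environment there was no test. The log2 ratio of the treated to the control array was taken, and genes well above background on at least 1 of the 2 arrays were counted at a threshold of 2-fold. A gene not well above background on one array has only a bound, computed against the higher of its own value and the lowest well-above-background value of that array (0 where the bound leaves no difference). "At least N-fold" marks such a bound here and in the tests, where it is taken between group means. The median of each gene list was placed among 10000 random lists of the same size matched on mean expression. The 30 gene lists were fixed by tag or by product name, and 29 had a member on the array. The list of peanut and Bacillus sequences matched 0 genes. Lists were tested with limma's camera (preset correlation 0.01), again with an estimated correlation, and with fry.

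The rule for named genes was the 10 genes with the largest change in each direction among those past the threshold, filled up with the genes of smallest p where fewer passed (reported as not passing). For the response across environments the direction also had to be shared by all 4 pairs. Within an environment it took the 5 largest ratios in each direction among genes well above background on both arrays. All members of the aflatoxin, cyclopiazonic acid and kojic acid clusters, the development regulators and the conidial genes could be named, and the 4 members of largest change of every other list. The groups, designs, lists, this rule and the alternative settings were fixed before the data were examined. The alternatives were normexp background correction (offset 50), quantile normalization, both together, median centring, the authors' deposited log2 values, no detection filter, a filter on all 8 arrays, other fold thresholds, other blocks and variance models, and leaving out each environment. A common floor for dim values and measured values in place of the bounds were added after seeing the data. Other tools were data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.

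Each fit was tested on simulated data with 12351 genes and the spread observed within the broths and within the kernels. There were 50 genes at each log2 change of 1, 2, 4 and 8. For the blocked fit no difference between broth and kernel responses was simulated, although the real spread of that fit holds it. The shares called by the blocked fit may thus be too high. The simulation was revised after its first outputs were seen. The share called was 0%, 40%, 72% and 90% for the response across environments (1 unchanged gene called), 0%, 6%, 34% and 72% for the broths (24 unchanged genes called) and 0%, 0%, 26% and 58% for the kernels (1 unchanged gene called). The difference between kernel and broth responses called 0% at every size with 200 changed genes, and was not simulated with more. MM against PDB gave 0%, 28%, 66% and 96% (69 unchanged genes called) and UF against Jinhua gave 0%, 12%, 62% and 84% (3 unchanged genes called). Kernels against broths called 0% at every size with 200 changed genes, and 5%, 33%, 68% and 91.1% with 4000 changed genes (146 unchanged genes called).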

Results

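Transcript levels of 13487 A. flavus genes were measured on 8 arrays, 1 treated with B. megaterium and 1 control in each of PDB broth, MM broth, Jinhua peanut kernels and UF peanut kernels. The 4 broth arrays shared slide 1 and scanner 1, and the 4 kernel arrays shared slide 2 and scanner 2. In the broths, 9063 genes (treated) and 10658 genes (control) were well above background in PDB, and 9296 and 10994 in MM. In the kernels the numbers were 11495 and 11296 for Jinhua, and 11821 and 11348 for UF. The treated broth arrays were dimmer than their controls. The 75th percentile of the signal was 496 against 1040 scanner units in PDB (2.10-fold) and 409 against 1680 in MM (4.11-fold), while the treated kernel arrays were slightly brighter (423 against 335, and 566 against 417). Spike-in probes (synthetic control transcripts) were brighter on the treated broth arrays, by 1.09 on the log2 scale in PDB (SD 0.50 over 10 probes) and 3.71 in MM (SD 1.34). On the kernel arrays the spike-ins lay near background, at log2 values of 1.43 to 2.14. Spots of one probe differed by a median SD of 0.04 to 0.06 (log2) on the broth arrays and 0.10 to 0.15 on the kernel arrays. With 1 array per group, no value within an environment has a replicate.

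**Figure D1:**
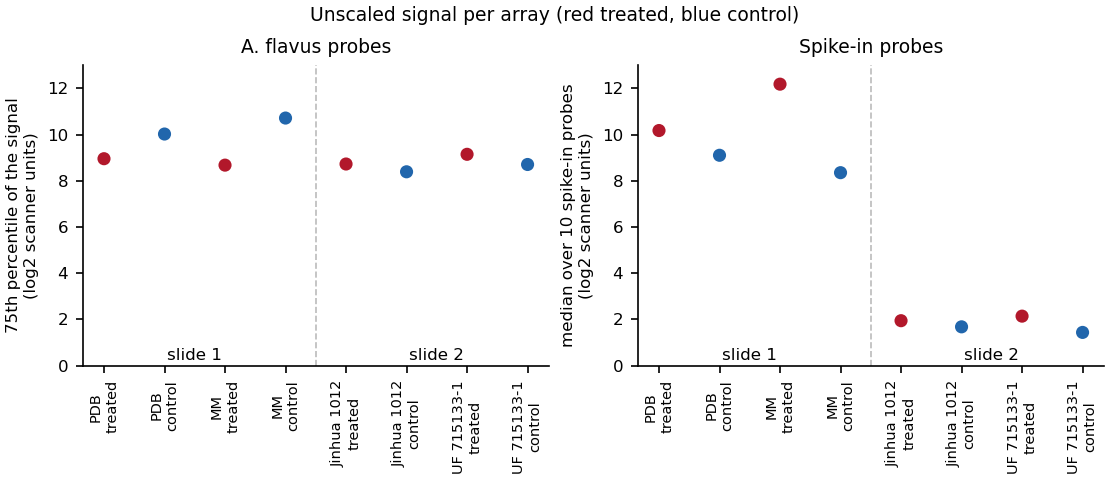
Unscaled signal per array in log2 scanner units, with the 75th percentile over A. flavus probes (left) and the median over 10 spike-in probes (right); red points are treated and blue points control arrays. The treated broth arrays lie below their controls for A. flavus probes and above them for spike-ins.

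The first question was how the fungal transcriptome differed with the bacterium in each environment. In PDB the largest ratios among genes with a product name and well above background on both arrays were those of 3 hydrolases and a nuclear pore protein. A maltase (AFLA_126900) was higher by a log2 ratio of 11.04, a cutinase (AFLA_023390), which cleaves plant cutin polyester, by 10.98, a lipase (AFLA_126740) by 10.68 and a nuclear pore glycoprotein p62 (AFLA_004810) by 11.13. A white collar protein (AFLA_116680), of a family of blue-light receptors, was at −7.68, a GliT-like thioredoxin reductase (AFLA_106850) at −7.65 and an alcohol dehydrogenase (AFLA_023780) at −7.20. In MM, an efflux pump (AFLA_013110) was higher by 11.20 and a phytanoyl-CoA dioxygenase family protein (AFLA_123810) by 8.64. The hydrophobin gene rodA, which encodes the rodlet layer of conidia, was at −9.53 in MM, an App1-like actin organization protein (AFLA_127680) at −7.75, a dimethylaniline monooxygenase (AFLA_095050) at −7.63 and a metallo-beta-lactamase domain protein (AFLA_105750) at −7.07. The kernels gave smaller ratios. In Jinhua a choline/ethanolamine kinase (AFLA_003780) was at 4.02, the zinc-binding oxidoreductase CipB (AFLA_042480) at 4.01 and a short chain dehydrogenase (AFLA_073880) at −3.52. In UF a tyrosinase (AFLA_108370) was at 3.71, an efflux pump (AFLA_000840) at 2.73, a monooxygenase (AFLA_136890) at −3.47 and an MFS transporter (AFLA_107060) at −3.13. The remaining named genes were hypothetical proteins, the largest ratio being that of AFLA_073020, at 14.61 in PDB and 9.54 in MM.

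In PDB 2046 genes were at least 2-fold higher and 2710 lower with the bacterium, 44.0% of the 10813 genes detected on either array. The counts were 3104 higher and 2634 lower in MM (51.5% of 11136), 427 and 473 in Jinhua (7.69% of 11703), and 460 and 293 in UF (6.30% of 11945). Among 7912 genes well above background on all 8 arrays the shares were 44.5%, 53.7%, 4.18% and 3.01%. The split depended on the scaling. Genes higher were 43.0% of those counted in PDB but 53.0% with normexp and the 75th percentile and 53.4% with median centring. They were 54.1% in MM but 68.0% with normexp and the 75th percentile, and 61.1% in UF but 48.7% with normexp. The median ratio of all tested genes, −0.02, 0.29, −0.03 and 0.02, became 0.55, 0.95, −0.15 and −0.15 with normexp and the 75th percentile, and 0.20 in PDB and 0.18 in MM with median centring. The log2 ratios of PDB and MM correlated at r = 0.40 over 12351 genes, those of the 2 kernels at 0.07, and the other pairs lay between −0.02 and 0.04. Over the 7912 genes detected on all 8 arrays r was 0.38 for PDB and MM, 0.14 for PDB and UF and 0.06 for the 2 kernels. The other pairs then lay between −0.03 and 0.03. Genes are not independent replicates.

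**Figure D2:**
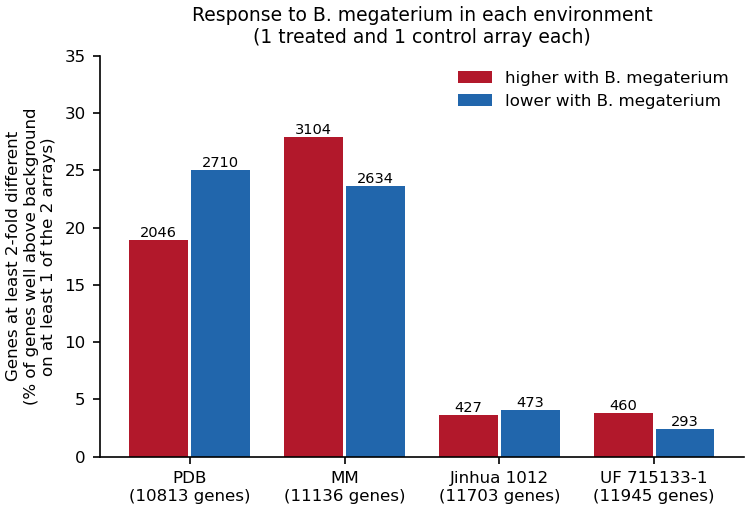
Genes at least 2-fold higher (red) or lower (blue) with B. megaterium in each environment, as a percentage of the genes well above background on at least 1 of its 2 arrays, with gene counts above the bars. The bars stand for 4756 genes in PDB and 5738 in MM, against 900 in Jinhua and 753 in UF.

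The aflatoxin cluster, the 29 neighbouring genes that make and regulate aflatoxin, was higher with the bacterium in both kernels. Of 26 cluster genes detected on all 4 kernel arrays, 24 were higher in both, with a median log2 ratio of 1.61 in Jinhua (SD 0.77 over genes) and 1.20 in UF (SD 0.41). The polyketide synthase gene aflC, at the start of the pathway, was at 2.23 and 1.79, the fatty acid synthase gene aflB at 1.86 and 1.53, and the ketoreductase gene aflD at 1.45 and 1.16. The late methyltransferase genes aflO and aflP were at 2.47 and 1.16, and at 1.61 and 1.51. The exceptions were aflT, a transmembrane transporter gene, at −0.66 in Jinhua and 0.25 in UF, and aflF at −0.09 and 0.52. The median over all detected members, 1.61 for 27 genes and 1.16 for 29, lay at percentile 100 of the random lists in both kernels.

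In the broths the cluster was mostly not well above background. Detected members numbered 7 (treated) and 15 (control) in PDB, and 7 and 13 in MM, against 26 to 29 on the kernel arrays. The median ratio was 0 in both broths, at percentiles 57.2 and 49.4, with bounds of 0 for several members. Under other settings it was as high as 0.36 in PDB. In MM it was 1.27 without a detection filter, where members at background enter too. Under the remaining settings the MM median lay between −0.01 and 0.02. With bounds included, 0 members were at least 2-fold higher and 4 lower in PDB, and 2 higher and 2 lower in MM. Members detected on both arrays went both ways. The genes aflB, aflC and aflY were higher, by 0.62, 0.71 and 0.68 in PDB and by 1.98, 1.00 and 1.27 in MM. The oxidase gene aflX was at −3.13 and −0.36, and aflNa at −0.83 and −1.07.

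The 2 regulators of the cluster were compared with each other. The co-activator gene aflS was at −3.83 in PDB and −4.04 in MM, while aflR, which encodes the cluster's DNA-binding activator, was at 0.36 and 0.02. In the kernels both were slightly higher, aflS at 0.68 and 0.30 and aflR at 0.63 and 0.27. The difference of the ratios, aflS minus aflR, was −4.18 in PDB, −4.05 in MM, 0.05 in Jinhua and 0.02 in UF. Its mean was −2.04 (SD 2.40, n = 4), with p = 0.5 in an exact two-sided sign-flip test whose smallest possible p is 0.125. The mean was −1.27 with normexp and quantile normalization, and between −2.74 (without Jinhua) and −1.33 (without PDB) when 1 environment was left out.

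**Figure D3:**
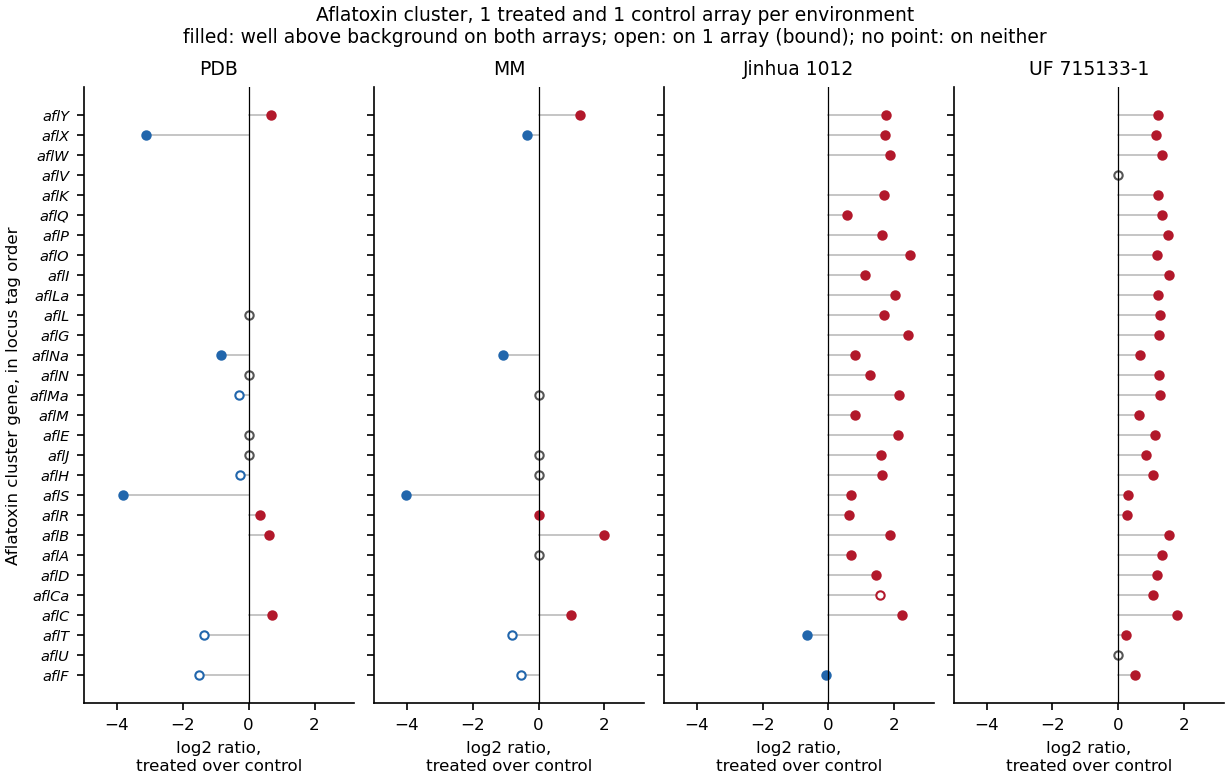
Log2 ratio of the treated to the control array for each aflatoxin cluster gene in the 4 environments; filled points were well above background on both arrays, open points on 1 (a bound) and genes without a point on neither. In both kernels most genes lie between 0.5 and 2.5, whereas in the broths aflS lies at −3.83 and −4.04.

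The other secondary metabolite clusters had their own pattern. Cyclopiazonic acid genes, which lie next to the aflatoxin cluster, were lower with the bacterium in both broths. The hybrid synthase gene cpaA was at −5.04 in PDB and −5.21 in MM, the prenyltransferase gene cpaD at −3.85 and −3.55, and the oxidoreductase gene cpaO at −4.18 in PDB (in MM it was detected on the control array only, with a bound of −3.99). The adjoining transporter AFLA_139460 was at least 1287-fold lower in PDB and at least 7.94-fold lower in MM. Over the kernels, cpaD was at −0.98 and −0.90 and cpaA at −0.93 and 0.25. The list medians were −4.61, −3.77, −0.95 (2 genes) and −0.89 in PDB, MM, Jinhua and UF. Those of the kernels were as small as −0.26 in Jinhua and 0 in UF under other settings. The ustiloxin B cluster (a cyclic peptide toxin) had medians of −0.79, −7.48, −1.69 and 0.14, with 16 of 17 members at least 2-fold lower in MM and 13 of 17 in Jinhua. The size depended on the setting, with medians as small as 0 in PDB, −2.03 in MM and −0.38 in Jinhua, and the UF value turned to −0.02. Members included a dimethylaniline monooxygenase gene (AFLA_095050) at −7.63 in MM and −2.07 in Jinhua. Kojic acid genes had their largest median in PDB (3.88), with the oxidoreductase gene kojA at 3.88, the transporter gene kojT at 5.39 and the regulator gene kojR at 0.91. In MM kojA was at −1.36 and kojR at −0.40, and the medians in the kernels were 0.17 (turning negative under 3 settings in Jinhua) and 0.18. The medians of the smaller lists were −0.26, −0.34, −0.91 and −0.24 for leporin (percentile 0.1 in Jinhua), −1.10, −1.69, −0.19 and −0.29 for aflatrem, −0.76, −1.17, −0.15 and −0.27 for aspergillic acid, and 0, −2.32, −0.01 and −0.62 for asparasone (1 or 2 genes). The leporin median in Jinhua was as small as −0.22 under another setting. Under other settings the sign turned for leporin in PDB, aflatrem and asparasone in MM, aflatrem and aspergillic acid in PDB, and aflatrem, aspergillic acid and asparasone in Jinhua.

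Some genes of asexual spore formation had lower values with the bacterium in the broths and others higher ones. In MM rodA was at −9.53 and con-6 at −3.18, and in PDB rodA was at least 132-fold lower. The regulator gene brlA, which starts conidiophore development, was at least 16.9-fold lower in PDB and at −1.93 in MM. In the kernels rodA was at 0.31 and 0.43 and brlA at 0.06 and 0.66. Of the others, con-10 was at 2.21 in PDB and 2.86 in MM, vosA at 1.55 and 1.52, and the spore pigment synthase gene wA at 1.55 in PDB and −1.90 in MM. The velvet regulator gene veA was at −0.61 in PDB and 2.20 in MM, laeA, a global regulator of secondary metabolism, at −0.89 and −1.11, and fluG at 0.15 and −1.86. List medians were −0.12, −0.95, −0.05 and 0.11 for conidial genes and −0.09, −0.67, −0.14 and 0.19 for development regulators. Signs turned under other settings in every environment for conidial genes, and in all but MM for development regulators. In PDB the conidial median was above 0 under 8 of 9 settings (up to 1.88) and below 0 only in the main one.

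Among growth-related groups, ribosomal protein genes stood lower in MM, with a median of −1.17 and 64 of 105 at least 2-fold lower, among them L6 (AFLA_068420, −2.79), L31e (AFLA_033690, −2.50) and S11 (AFLA_044170, −2.31). Their medians were −0.09 in PDB (sign turning under 3 settings), 0.17 in Jinhua (percentile 100 of the random lists, but 0.00405 under another setting) and −0.04 in UF. Heat shock proteins and chaperones had medians of −0.37, −0.92, 0.10 and 0.08, with the co-chaperone Cdc37 (AFLA_025980) at −4.06 and a chaperonin (AFLA_106310) at −4.92 in MM, while Hsp12 (AFLA_052860) was at −4.05 in PDB and 3.85 in MM. Oxidative phosphorylation genes had medians of −0.52, −0.36, 0.03 and 0.13, and glycolysis genes −0.66, −0.36, −0.01 and −0.14, with phosphofructokinase (AFLA_119290) at −4.42 in MM. In PDB the glyoxylate cycle enzymes malate synthase (AFLA_049390) and isocitrate lyase (AFLA_052400) were at −4.40 and −3.27, and the list of fatty acid oxidation and glyoxylate genes had medians of −0.31, 0.58, 0.17 and 0.02. Proteasome genes had medians of −0.24, 0.55, −0.07 and 0.13. In Jinhua, the signs of the heat shock, oxidative phosphorylation, glycolysis, fatty acid and proteasome medians turned under at least 1 other setting, as did the proteasome median in PDB and the fatty acid median in UF.

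Iron uptake and siderophore genes had the same median in both kernels, −0.42, at percentile 0 of the random lists. In Jinhua a siderophore transporter (AFLA_010640) was at −1.83 and the acetylase AceI (AFLA_010600) at −1.44. In UF the ferric-chelate reductases AFLA_008640 and AFLA_041700 were at −1.10 and −1.08. Another siderophore transporter, AFLA_137920, was higher in both, at 1.99 and 2.17. The broth medians were −0.04 and 0. Plant cell wall-degrading enzymes had a median of −0.31 in Jinhua (percentile 0.02; as small as −0.05 under another setting), with a pectate lyase (AFLA_057770) at −1.72 and a pectin lyase (AFLA_007720) at −1.69. Elsewhere the median was −0.13 in PDB, 0 in MM and −0.09 in UF, although the cutinase AFLA_039350 was at 6.64 in PDB and 7.51 in MM. In MM 24 of 63 detected wall-degrading enzymes were at least 2-fold higher and 6 lower, against 3104 and 2634 of all 11136 detected genes. Their MM median was as high as 1.20 under another setting. Among proteases, with medians of 0.06, 0.15, 0.05 and 0.09, aminopeptidase Y (AFLA_034640) was at 7.71 in PDB and 4.20 in MM. Drug efflux genes had medians of −0.35, −0.35, −0.01 and 0.02, and the gliotoxin-type efflux gene GliA (AFLA_039180) was at −5.02 in PDB and −6.24 in MM. In ergosterol synthesis, the target of azole antifungals, medians were −0.24, −0.56, −0.18 and −0.13, with squalene monooxygenase Erg1 (AFLA_061500) at −4.30 in MM. Antioxidant enzymes had medians of −0.52, −0.02, 0.01 and 0.07, with the spore catalase CatA (AFLA_056170) at −4.15 in PDB. Secondary metabolite backbone enzymes had medians of −0.67 (percentile 0.03; 0 under another setting), −0.10, −0.22 (−0.04 under another setting) and 0.18, including a polyketide synthase (AFLA_105450) at −6.54 and a prenyltransferase (AFLA_083250) at 7.65 in PDB. The remaining medians were −0.44, 0, −0.05 and 0.07 for cytochrome P450, 0, 0.31, 0.09 and 0.02 for lipases, −0.39, 0.27, −0.04 and −0.06 for sugar transporters, 0, 0, −0.03 and −0.08 for amino acid transporters, 0, 0, 0.05 and 0.08 for fungal cell wall synthesis (chitin synthase AFLA_137200 was at 2.22 in Jinhua), and −0.16, 0.01, −0.12 and −0.03 for nitrogen assimilation. Signs turned under at least 1 other setting for the P450, antioxidant, lipase, drug efflux and nitrogen medians in both kernels, for antioxidants in MM, nitrogen in PDB, sugar and amino acid transporters and cell wall synthesis in Jinhua, and proteases and backbone enzymes in UF.

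**Figure D4:**
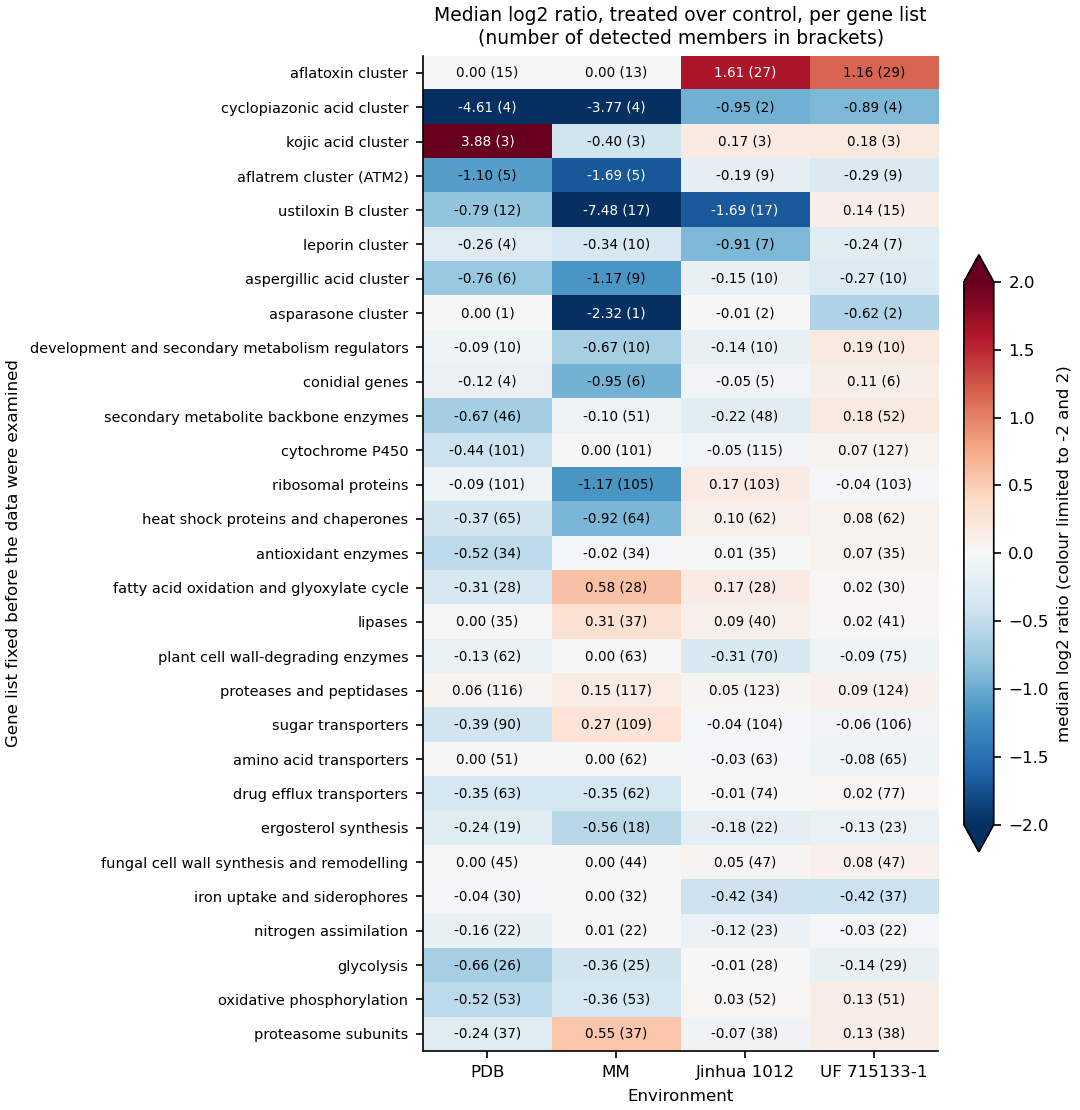
Median log2 ratio of the treated to the control array for each gene list and environment, with the number of detected members in brackets and the colour limited to between −2 and 2. The aflatoxin cluster stands at 1.61 and 1.16 in the kernels, and the cyclopiazonic acid cluster at −4.61 and −3.77 in the broths.

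Whether any gene responded alike in the 4 environments was asked with environment as a block. The hypothetical gene AFLA_013120 was among those of smallest p, higher by 5.50 on the log2 scale (SE 0.88; 4.31 with the common floor, a setting added after seeing the data). Values of aflG (1.82, SE 0.39) rest in part on background, since no broth array was well above background for it, and with the common floor it was at 0.91. Lower values included those of a C-4 methyl sterol oxidase of ergosterol synthesis (AFLA_121580, −2.16), a subtilisin (AFLA_104430, −2.52, or −0.96 with the common floor), an MFS transporter (AFLA_124130, −1.87) with its neighbour, a beta lactamase domain protein (AFLA_124140, −2.56), and an integral membrane protein (AFLA_060040, −2.20, or −1.14 with the common floor). None passed, since limma called 0 of 12351 genes (smallest adjusted p = 0.638), with 620 at an unadjusted p under 0.05 where 617.55 are due by chance.

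At the level of lists, the aflatoxin cluster stood above the other genes (median 1.23, camera adjusted p = 6.55e-07), with 14 of 27 members higher when adjusted over the list alone. The cyclopiazonic acid (−2.57, adjusted p = 0.000436, 3 of 4 lower over the list alone) and ustiloxin B clusters (−2.64, adjusted p = 1.80e-07) stood below, as did backbone enzymes (−0.48, adjusted p = 0.00667), ribosomal proteins (−0.30, adjusted p = 3.06e-05) and heat shock proteins (−0.38, adjusted p = 0.0215). With an estimated correlation no list passed, each of these 6 having an adjusted p = 0.664, and fry called 0 lists. The aflatoxin median and the count of 14 rest in part on dim broth values. Only 7 cluster genes were well above background on each treated broth array, so the 14 were not all measured as higher there. With the common floor the aflatoxin median was 0.66, and backbone enzymes (camera adjusted p = 0.0738) and heat shock proteins (adjusted p = 0.123) did not pass. Means and medians differed in sign for aflatrem, sugar transporters and ergosterol synthesis.

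In the broths alone 19 genes passed, 10 higher and 9 lower. The lipase AFLA_126740 was higher by 10.13 on the log2 scale (SE 0.61, adjusted p = 0.0456), the cutinase AFLA_039350 by 7.08, an HMG-CoA reductase (AFLA_126760), of the type that supplies sterol precursors, by 6.83, an amidotransferase (AFLA_126380) by 6.13 and a cytochrome P450 (AFLA_126650) by 5.96. An RTA1 domain protein (AFLA_124230), of a family linked to lipid and drug resistance in yeast, was at least 17711-fold higher and an F-box protein (AFLA_059420) at least 12.96-fold. The conidial hydrophobin gene rodA was lower (−9.32, SE 0.38, adjusted p = 0.0241; on the treated arrays it was well above background on 1 of 2), as was the GliT-like thioredoxin reductase (AFLA_106850, −7.35). An NmrA-like protein (AFLA_121490) was at least 13.3-fold lower and a LysR family regulator (AFLA_125770) at least 26.0-fold. The others were hypothetical proteins, and an O-methyltransferase (AFLA_010550) just missed the threshold (at least 79.1-fold lower, adjusted p = 0.0510). None of the 19 passed with the common floor (0 genes, 2945 unadjusted), though all kept their direction. With it AFLA_126760, AFLA_126380 and AFLA_106850 kept the same log2 value and AFLA_039350 was at 6.33. The dimmer AFLA_124230 and AFLA_059420 were at 12.16 and 1.74. Simulated data with this spread gave 24 calls among unchanged genes. Beside them, 0, 3, 17 and 36 of 50 changed genes were called at log2 changes of 1, 2, 4 and 8. The spread of this fit was pooled with the kernel ratios, which were smaller. The 19 calls may thus hold more false ones than the threshold allows. Of the calls 52.6% were higher, but 61.5% with normexp and the 75th percentile, 44.7% without a detection filter, 39.4% with quantile normalization, 38.5% with median centring and 39.1% with the authors' deposited values.

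Over the broth lists, all 4 cyclopiazonic acid genes were lower when adjusted over the list alone (cpaA −5.13, SE 0.46; median −4.60, camera adjusted p = 0.000533). Ustiloxin B (−4.44, adjusted p = 3.50e-05), backbone enzymes (−0.68, adjusted p = 0.00810), ribosomal proteins (−0.70, adjusted p = 6.14e-07), heat shock proteins (−0.75, adjusted p = 0.00607) and oxidative phosphorylation (−0.52, adjusted p = 0.0103) also passed downwards, each with an adjusted p = 0.862 with an estimated correlation. Backbone enzymes and oxidative phosphorylation lost the call with the common floor (adjusted p = 0.0551 each). The aflatoxin cluster did not pass (0.85, adjusted p = 0.619), and its median was 0 with the common floor. By fry, which asks whether members move one way on balance, cyclopiazonic acid, ergosterol synthesis and oxidative phosphorylation passed downwards and proteases upwards (adjusted p = 0.0216 each), although the median of the ergosterol list was 0.13 and its mean −0.47.

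In the kernels alone the smallest p-values among genes with a product name were those of CipB (AFLA_042480, 3.22, SE 0.53), 2-oxoglutarate dehydrogenase (AFLA_084110, 2.40), a polyadenylate-binding protein (AFLA_109310, at least 1.97-fold higher) and aflC (2.01, SE 0.39). With the common floor AFLA_109310 was at only 0.24 on the log2 scale, and it turned negative with normexp. On the other side stood AFLA_060040 (−2.29), a tryptophan permease (AFLA_052980, −2.14) and the ferric-chelate reductase Fre2 (AFLA_075950, at least 3.37-fold lower). With the common floor the permease was at −0.66 and Fre2 at −0.67. None passed. The count by limma was 0 (smallest adjusted p = 0.999973), with 143 genes at an unadjusted p under 0.05 where 617.55 are due by chance. The spread of this fit was pooled with the broth ratios, which were larger. Median absolute log2 ratios were 0.99 in PDB and 1.24 in MM, against 0.30 in Jinhua and 0.26 in UF. The lack of calls therefore cannot show that no gene responded in the kernels. Among lists the aflatoxin cluster stood above other genes (median 1.44, camera adjusted p = 8.22e-35) and so did oxidative phosphorylation (0.16, adjusted p = 0.0380). Iron uptake (−0.51, adjusted p = 0.000114), cyclopiazonic acid (−0.71, adjusted p = 0.0116), leporin (−0.45, adjusted p = 0.0130) and plant cell wall-degrading enzymes (−0.24, adjusted p = 0.0380) stood below. With an estimated correlation the adjusted p was 0.604 for aflatoxin, iron, leporin and oxidative phosphorylation, 0.611 for cyclopiazonic acid and 0.841 for wall-degrading enzymes. By fry 0 lists passed. The cyclopiazonic acid call was also lost with the common floor (adjusted p = 0.174).

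The test of the difference between kernel and broth responses passed for no gene. Among the genes of smallest p, rodA was higher in the kernels relative to the broths by 9.69 (SE 0.54, adjusted p = 0.0949; 8.36 with the common floor) and the GliT-like gene AFLA_106850 by 7.07. On the other side stood the lipase AFLA_126740 (−10.60, or −8.45 with the common floor) and the RTA1 gene AFLA_124230 (adjusted p = 0.0949), which was not well above background on the control broth arrays and was at −12.14 with the common floor. The aflS difference was 4.42 (SE 0.54, adjusted p = 0.175). The count was 0 of 12351 by limma, with 2114 genes at an unadjusted p under 0.05 where 617.55 are due by chance. A simulation with 200 changed genes called 0% even at a log2 change of 8. It does not give the share called when more genes change, which was not simulated for this test. By camera 7 lists passed, all higher in the kernels relative to the broths. They were aflatoxin (0.73, adjusted p = 0.00280), cyclopiazonic acid (4.08, adjusted p = 0.000735), ustiloxin B (3.61, adjusted p = 0.000735), backbone enzymes (0.63, adjusted p = 0.00975), ribosomal proteins (0.73, adjusted p = 7.68e-07), heat shock proteins (0.85, adjusted p = 0.00280) and oxidative phosphorylation (0.56, adjusted p = 0.00272). With an estimated correlation the adjusted p was 0.832 for aflatoxin and 0.831 for the other 6, and fry called 0. Backbone enzymes lost the call with the common floor (adjusted p = 0.0971).

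Kernels differed from broths in 2348 genes, 1719 higher and 629 lower, in means over both treatments. The control arrays alone gave 1645 genes. The aflatoxin cluster rose together, with 23 of 27 members passing (26 adjusted over the list alone) and a median of 6.24. Among them aflO was at least 2080-fold higher, aflS higher by 3.71 and aflR by 2.58. The values of aflL (11.47) and aflJ (11.41) rest on broth arrays mostly at background and were 9.14 and 9.51 with the common floor. Of 6 conidial genes 4 were higher too, among them rodA (9.76) and con-6 (7.43), while con-10 was at −1.84 and did not pass, and the development genes wetA (4.72) and abaA (3.35) rose while veA fell (−5.99). Enzymes acting on plant polymers included a mannanase (AFLA_038730, 13.42, SE 0.47, adjusted p = 0.0147; 11.93 with the common floor) and an endoglucanase (AFLA_105910, 9.81), with 23 of 78 wall-degrading enzymes higher and 1 lower. A CipC-like protein (AFLA_019180) was at least 2328-fold higher. Genes lower in kernels included an alcohol dehydrogenase (AFLA_008880, at least 995-fold), an Hsp30-like protein (AFLA_037820, −9.81), the HMG-CoA reductase AFLA_126760 (at least 186-fold), a deuterolysin-type metalloprotease (AFLA_065450, at least 587-fold), a siderophore enzyme (AFLA_102400, −8.69) and enolase (AFLA_037480, −4.45).

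By camera, aflatoxin (adjusted p = 1.71e-10) passed upwards, and cyclopiazonic acid (median −4.13, 2 of 4 lower, adjusted p = 0.0154), heat shock proteins (−0.69, 17 of 64 lower and 1 higher, adjusted p = 0.000375) and oxidative phosphorylation (−0.44, 6 of 53 lower, adjusted p = 0.0154) downwards, each with an adjusted p = 0.874 with an estimated correlation. In lists that did not pass, members higher and lower numbered 32 and 2 of 128 for cytochrome P450, 19 and 4 of 81 for drug efflux, 13 and 3 of 67 for amino acid transporters, 14 and 6 of 119 for sugar transporters, 10 and 0 of 105 for ribosomal proteins, and 10 and 12 of 127 for proteases. Over all 12351 tested genes 1719 were higher and 629 lower. The medians of the remaining lists were 5.54 for conidial genes, 5.07 for kojic acid, 2.88 for ustiloxin B, 2.55 for aflatrem, 1.90 for aspergillic acid, −1.87 for leporin, −1.05 for development regulators, 1.39 for iron uptake, 0.99 for wall-degrading enzymes, 0.78 for lipases, 0.65 for nitrogen assimilation and 0.53 for antioxidant enzymes. By fry cytochrome P450 and drug efflux passed upwards and heat shock proteins downwards (adjusted p = 0.0442 each). Oxidative phosphorylation did not pass with the common floor (adjusted p = 0.0774), which left 1868 calls. Slide, scanner and time of growth go with the substrate here and cannot be told apart from it. Of all calls 73.2% were higher in kernels, but 53.3% with quantile normalization, 56.8% with median centring, 58.2% with normexp and quantile normalization and 43.5% among genes detected on all 8 arrays, where 554 genes passed.

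Between MM and PDB 1192 genes passed, 734 higher in MM and 458 lower. Each medium had only 1 treated and 1 control array. The spread of this fit took in the kernel pairs, whose ratios were smaller, so it may be too small for the broths. In simulated data 69 unchanged genes were called, beside 0, 14, 33 and 48 of 50 at log2 changes of 1, 2, 4 and 8. The adjusted p-values may thus be too low, and the 1192 calls may hold more false ones than the threshold allows. Highest in MM were an alcohol dehydrogenase (AFLA_035580, 13.12, SE 0.57, adjusted p = 0.00175), an extracellular lipase (AFLA_122390, 12.28), a myo-inositol transporter (AFLA_013820, at least 666-fold), a pantothenate transporter (AFLA_064710, at least 827-fold), a GMC oxidoreductase (AFLA_127520, at least 1383-fold) and the leporin cluster P450 AFLA_066930 (11.07). Lower in MM were a hydrophobin family protein (AFLA_131460, at least 2635-fold), a gibberellin 2-oxidase (AFLA_064270, −11.47) with an O-methyltransferase close by in tag order (AFLA_064290, −11.12), and an oligopeptide transporter (AFLA_015780, −10.89). In nitrogen assimilation 3 genes were higher and 5 lower of 22, the latter including the nitrate reductase NiaD (AFLA_018810, −8.68), the nitrite reductase NiiA (AFLA_018800, −6.62) and the ammonium transporter MepA (AFLA_068600, −8.04). Of the kojic acid genes, kojA (−5.27) and kojR (−2.86) were lower. The glycolytic GAPDH gene AFLA_042390 was at −9.39 and the early conidiation gene fluG at 3.52.

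By camera 9 lists passed. Higher in MM were leporin (median 4.75, 7 of 9 passing, adjusted p = 8.28e-09), ustiloxin B (4.50, 1 of 17, adjusted p = 9.41e-05), aspergillic acid (2.87, 3 of 10, adjusted p = 0.0121), fatty acid oxidation and glyoxylate (1.79, 7 of 30, adjusted p = 0.00123), ribosomal proteins (1.37, 11 of 105 and 41 adjusted over the list alone, adjusted p = 1.31e-06), development regulators (1.22, 1 of 10, adjusted p = 0.0224) and sugar transporters (1.14, 33 higher and 14 lower of 119, adjusted p = 0.00344). Lower were kojic acid (−4.88, adjusted p = 0.00528) and ergosterol synthesis (−0.38, adjusted p = 0.0396). With an estimated correlation the adjusted p was 0.209 for leporin and between 0.456 and 0.586 for the others. By fry 10 lists passed, among them leporin (adjusted p = 0.00199), nitrogen assimilation downwards and fungal cell wall synthesis upwards (adjusted p = 0.00316 each). Aspergillic acid did not pass by camera with the common floor (adjusted p = 0.0928). Of all calls 61.6% were higher in MM, but 51.4% with normexp and the 75th percentile, 50.8% with quantile normalization, 49.1% with both, 50.7% with median centring and 51.2% with the authors' deposited values. The common floor left 624 calls, 485 of them shared, and the simulation called 69 unchanged genes.

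UF and Jinhua kernels, named resistant and susceptible, differed in no single gene past the threshold (0 genes by limma, smallest adjusted p = 0.811). At an unadjusted p under 0.05 there were 368 genes, where 617.55 are due by chance. The spread of this fit took in the broth pairs, whose ratios were larger, so it cannot show that no gene differed. The smallest p-values were those of 2 extracellular dioxygenases, AFLA_020430 (5.17, SE 0.62) and AFLA_131820 (5.03), and an amino acid transporter (AFLA_013580, 4.08), all higher in UF, and the mannosidase DCW1 (AFLA_116700, −2.97) was lower. The aflatoxin cluster stood higher in UF than the other genes did (median 2.25, camera adjusted p = 1.04e-40, but adjusted p = 0.527 with an estimated correlation), with 18 of 27 members higher when adjusted over the list alone, among them aflP (2.77) and aflD (2.99). On the control arrays 24 of 26 cluster genes were higher in UF (median 2.43), and on the treated arrays 26 of 26 (median 2.02). Iron uptake genes also stood higher (0.53, adjusted p = 8.55e-06), with the ferric-chelate reductase AFLA_041700 at 3.27 and a peptide synthetase (AFLA_010620) at 2.25, and ustiloxin B lower (−1.95, adjusted p = 0.000285). The adjusted p with an estimated correlation was 0.550 for iron and 0.849 for ustiloxin B. With the common floor the ustiloxin B call was lost (adjusted p = 0.0618). By fry 0 lists passed.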

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

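The explanations in this part were tested with values chosen only after the result was seen, while the fit of ratios and the scalings and filters they draw on were fixed beforehand.

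Among list medians (at least 3 detected members) and members of the fully named clusters detected on all 8 arrays, 6 had both broth ratios one way and both kernel ratios the other. Genes with a bound in some environment, such as rodA and brlA, were not considered. The values were picked for this pattern and are given as the mean of the kernels minus the mean of the broths, on the log2 scale. The aflatoxin genes aflS, aflX and aflNa differed by 4.42, 3.18 and 1.67. In the fit of ratios the aflS difference had an adjusted p = 0.175. The list medians differed by 0.732 for heat shock proteins and chaperones, 0.519 for oxidative phosphorylation and 0.309 for antioxidant enzymes. In the camera test of this difference the adjusted p was 0.00280 for heat shock proteins, 0.00272 for oxidative phosphorylation and 0.480 for antioxidant enzymes, and none passed with an estimated correlation. The antioxidant value rests on medians near 0 (−0.02 in MM and 0.01 in Jinhua). Of 9 settings, its sign turned under 5 in MM and 6 in Jinhua. The Jinhua medians of heat shock proteins and oxidative phosphorylation turned negative under 1 setting each (to −0.02 and −0.01). Of 7912 genes detected on all 8 arrays, 1217 (15.4%) had such opposite directions, and 373 of these were at least 2-fold in both broths. A share of 12.5% would be due by chance if the 4 ratios were independent, but PDB and MM correlated at r = 0.38 over these genes, which raises it, so no excess is claimed.

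The treated broth arrays were dimmer for A. flavus probes. Weaker labelling, hybridisation or scanning of the whole treated array at equal amounts of spike-in is argued against by the spike-ins, which were brighter there by at least 1.09 on the log2 scale. This assumes that equal amounts were added to each sample, which the sources used here do not state. Less A. flavus messenger RNA in the labelled RNA stays open. The share of genes with a lower unscaled signal on the treated array (79.9% in PDB and 87.4% in MM) only restates the dimness and cannot decide it. Whether bacterial RNA took up the difference is open too, because the array annotation names no bacterial probe.

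The aflatoxin cluster was higher with the bacterium in both kernels. Normalization between arrays is argued against, the lowest median ratio over the scalings and filters being 1.07. Variation between batches of kernels with no effect of the bacterium stays open, since the control arrays of UF and Jinhua differed by 2.43 for the same genes, more than either treatment ratio, and each kernel has 1 array per treatment. Exchanged treated and control labels in the kernels cannot be told apart from a true difference, because mean broth and mean kernel responses correlated at r = 0.00895 over genes. An effect of the bacterium on the cluster in kernels stays open as a hypothesis.

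Many more genes were at least 2-fold different in the broths than in the kernels. Dim genes near the detection limit are argued against as the cause, because among genes well above background on all 8 arrays the lowest broth share was still 10.6 times the highest kernel share. Measurement noise of the spots is argued against too, with the highest spot SD of the broth arrays at 0.589 times the lowest of the kernel arrays. Slide, scanner and time cannot be told apart from the substrate, since 0 environments were measured on both slides. The treated broth arrays were also dimmer than their controls, 2.10-fold in PDB and 4.11-fold in MM, while the treated kernel arrays were slightly brighter. Whether this imbalance widened the broth ratios was not tested. The substrate itself stays open as a biological difference and was not tested.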

How the results depend on the processing

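The common floor and the measured values in place of the bounds were chosen only after the data were seen, while the other settings were planned. No paired analysis was possible because the groups share only replicate number 1, if pairs are taken by that number. Pairing by environment is in the fits themselves, and without that block 0 genes passed across environments (100 unadjusted). The brightest-probe alternative was not run, since each gene has 1 probe. The authors' values were not used for kernels against broths, since their medians differed between the broth and the kernel columns. For genes with a product name, 37 named results were past the threshold, each counted per comparison. Of their 404 values under other settings, 327 kept it, 77 lost it and 0 turned. The aflatoxin medians in both kernels kept their direction under each scaling and filter. The cause of the changes below was not tested, except where fewer genes or environments enter by construction.

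Genes changed in the broths (19) numbered 301 with normexp and the 75th percentile, 33 with quantile normalization, 0 with normexp and quantile, 117 with median centring, 69 with the authors' values, 38 without a detection filter, 0 with detection on all 8 arrays and 0 with the common floor. MM against PDB (1192) gave 661 with normexp, 613 with normexp and quantile, 641 with detection on all 8 arrays and 624 with the common floor. Kernels against broths (2348) gave 554 with detection on all 8 arrays and 3914 with environment as a random block. Camera lists for the response across environments fell from 6 to 3 with detection on all 8 arrays.

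Genes at least 2-fold different numbered 256 in Jinhua and 152 in UF with normexp; 2691, 3685, 349 and 192 in PDB, MM, Jinhua and UF with normexp and quantile; 1415 and 1291 in the kernels without a filter; and 331 and 238 with detection on all 8 arrays. At 1.5-fold the kernel counts were 2649 and 2170, and at 3-fold the 4 counts were 2717, 3682, 333 and 230. The cyclopiazonic acid median was −2.45 (normexp) and −2.53 (normexp and quantile) in MM. In Jinhua it was −0.42 (normexp), −1.06 (quantile), −0.26 (normexp and quantile), −0.87 (median centring), −1.06 (authors' values) and −0.73 (no filter), and in UF −0.10 (normexp and quantile) and 0 (common floor). In the kernels AFLA_109310 turned from 2.84 to −0.10 and AFLA_111300 from 1.82 to −0.28 with normexp, neither past the threshold.

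Leaving out 1 environment gave 0 to 3210 genes for the difference of responses (3210 without PDB, 574 without MM), 5 to 5026 for the broths (5026 without PDB, 2877 without MM, 5 without either kernel) and 0 to 5864 for kernels against broths (5864 without PDB, 5530 without MM, 0 without either kernel). The single broth or kernel left is then assumed to vary like the others. The median difference of all genes moved from 0.24 to −0.21 for kernels against broths and from 0.17 to −0.12 for MM against PDB with median centring. Dim genes limit the broths most, where 67.2% and 68.9% of genes were well above background on the treated arrays.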

Other observations

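The test on chance below for kernels against broths was written before its result was seen and the one for the response across environments after it.

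Some genes went opposite ways in the kernels of the 2 peanut lines. In Jinhua the polyketide synthase genes AFLA_062860 and AFLA_062820 were at −2.48 and −2.23 with the bacterium, and in UF at 1.67 and 2.35. The iron superoxide dismutase A gene (AFLA_027580) was at −1.01 and 1.53 in the same order, and a GAPDH gene (AFLA_101470) at −1.20 and 1.92. The C-4 methyl sterol oxidase AFLA_121580 was lower in all 4 environments (−2.88, −3.00, −0.96 and −1.78). These values are single ratios of 1 array to another.

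Other metabolic and stress genes had large ratios in the broths. The formamidase gene fmdS (AFLA_043010) was at 2.88 in PDB and 3.49 in MM, and the acyl-CoA oxidase AFLA_115890 at 5.17 in PDB. The mycelial catalase Cat1 (AFLA_090690) was at 4.06 in MM and the catalase-peroxidase Cat2 (AFLA_122110) at 4.18 in PDB, whereas Cu,Zn superoxide dismutase (AFLA_099000) was at −3.73 in PDB and thioredoxin TrxA (AFLA_132540) at −4.09 in MM. The cell wall galactomannoprotein Mp1 (AFLA_039410) was at 5.14 and 2.73.

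For the response across environments, 8 of the 8 splits that part each environment's pair of arrays gave as many genes, the real one and the highest other both giving 0, and 8 splits are too few for a share under 0.05. At an unadjusted p the real split gave 620 genes and the highest other 636. Of the 24 splits that part only 2 pairs, the highest gave 2183 genes, a split that sets treated against control broths while keeping kernel pairs together. Its contrast is thus the broth response alone, and the kernel pairs enter only the spread. Their median absolute log2 ratios were 0.30 and 0.26, against 0.99 in PDB and 1.24 in MM. For kernels against broths, 1 of the 3 splits of the environments gave as many genes (2348 for the real split, 0 for the highest other), and 3 splits are too few for a share under 0.05.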
